A study of Mus musculus with 2 samples.

How the data were processed

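The series holds 2 single-cell RNA libraries of immune cells that had infiltrated the gingiva of C57BL/6 mice, 1 from wild-type (WT) animals and 1 from animals labelled Otud1-/-, in a study of experimental periodontitis. Per the labels' protocols, cells were partitioned with the 10x Genomics Chromium system and libraries were made with the 3′ gene expression chemistry, version 3.1. In this assay each transcript is tagged near its 3′ end with a cell barcode and a unique molecular identifier (UMI). The number of animals pooled into each library, their sex, whether the gums of both groups had been treated alike, and the part of Otud1 that had been deleted were not given in the sources used here.

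The deposited values were raw UMI counts per gene and cell barcode, as whole numbers with no normalisation, per the file headers and the values themselves. Per the submitters' processing notes, Cell Ranger 5.0.0 and Seurat 3.2.3 were used with the mm10 genome build. Per the file headers, the count matrices came from Cell Ranger 6.0.1. The matrices held barcodes called as cells, and no cell annotation was used here. The WT library had 13267 barcodes, 44878537 UMIs and a median of 2241 UMIs per barcode. The library labelled Otud1-/- had 8109 barcodes, 44083735 UMIs and a median of 3716. The lowest barcode held 776 UMIs in the WT library and 500 in the other.

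Groups, filters, gene lists, cell type markers, the rule for named genes and the first set of other settings were fixed before the data were examined. Cells with at least 200 genes and at most 15% mitochondrial UMIs were kept. Doublets were sought in each library with a Scrublet-type simulation of 2 artificial doublets per cell. Its automatic threshold marked 0 cells of the WT library and 2 of the library labelled Otud1-/-, too few to have worked. As set out beforehand for that case, the highest scores at a rate of 0.8% per 1000 barcodes were removed, which took 1355 WT cells (10.6%) and 450 cells of the other library (6.49%). This left 11414 WT cells with a median of 2082 UMIs and 6486 cells with a median of 4169.5 UMIs. Both libraries were clustered together without integration, on log-normalised counts (scale 10000), 2000 variable genes, 30 principal components, a shared-neighbour graph of 20 neighbours and Leiden clustering at resolution 1. Otud1, sex-linked genes, immunoglobulin and T cell receptor segments, ribosomal and mitochondrial genes were left out of the variable genes.

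Clusters were named from 22 fixed sets of cell type markers, by a naming rule that was set after seeing the data. Genes detected in at least 25% of a cluster were ranked by their ratio of CPM (UMIs scaled to the standard common total) to all other kept cells, with a prior of 1 CPM. A cluster took the class with the most markers among its top 50 genes, given at least 3 such markers, no tie and no other class with more markers among its top 10. A class name therefore means that a cluster resembled that cell type by these markers (neutrophil-like, B-like and so on), and the shares would differ under other names. The 12 classes so named were neutrophil, B, T, NK, dendritic, plasmacytoid dendritic, monocyte/macrophage, plasma, mast cell/basophil, group 2 innate lymphoid (ILC2), erythroid and fibroblast. The other marker sets, which included eosinophils, osteoclasts, platelets, epithelium and endothelium, named no cluster.

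With 1 library per genotype there are no replicates, and no test was run. UMIs were summed per class and library, scaled to CPM of the class total, and compared as a log2 ratio of the library labelled Otud1-/- over WT with a prior of 0.5 CPM. Ratios carry exact conditional binomial 95% intervals, CPM values exact Poisson intervals, and shares of cells exact Clopper-Pearson intervals. All of these cover counting error only. Genes were compared if their mean was at least 50 CPM and the higher library had at least 100 UMIs. Genes were then counted at a ratio of at least 1.5 in either direction. Named genes were, by size of the log2 ratio alone, the 12 highest and 12 lowest in neutrophils and the 4 highest and 4 lowest in each other class with at least 100 cells in both libraries. A gene below 10% of its CPM in another named class of at least 100 cells in the same library may be background RNA. Such a gene was not named by this rule. Erythroid cells (86 and 62) and fibroblasts (37 and 32) were too few in both libraries to be used for this. In the library labelled Otud1-/- so were plasma, plasmacytoid dendritic, mast cell/basophil and ILC2 cells. Background RNA from these classes was therefore not fully screened. Immunoglobulin, T cell receptor, sex-linked, Otud1 and predicted genes were also left out of naming. For 30 gene lists, members with a mean of at least 20 CPM were used, the 3 members with the largest ratio could be named, and the median log2 ratio was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Of these, 6 lists on protein transport were also pooled into 1 list. The sex-linked genes (Xist and 4 Y-linked genes) served as a check of the animals.

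The rule for counts and intervals was tested on simulated counts drawn from the real class means, with 200 changed genes per comparison. In the neutrophil class, 2211 simulated genes were compared, 87 of 87 genes changed 2-fold and 87 of 87 changed 3-fold passed the limit, and 3 of 2037 unchanged genes did. Cluster 5 of the neutrophils gave 61 of 63, 67 of 67 and 9 of 1189 on 1319 genes. B cells gave 92 of 92, 81 of 81 and 0 of 2386 on 2559 genes, and T cells 87 of 87, 83 of 83 and 0 of 2373 on 2543. NK cells gave 77 of 77, 79 of 79 and 3 of 1339 on 1495 genes, dendritic cells 90 of 90, 86 of 86 and 0 of 2241 on 2417, and monocytes/macrophages 85 of 85, 86 of 86 and 0 of 2456 on 2627. In the neutrophil simulation 95.5% of intervals of unchanged genes held the true value, and 4 of 200 unshifted lists lay outside percentiles 2.5 to 97.5. The simulation holds counting noise alone and no difference between animals.

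Other settings fixed beforehand were at least 500 genes, at most 5% mitochondrial UMIs, no doublet removal, Leiden resolutions 0.5 and 2, clustering each library alone, thinning each cell to 1000 UMIs, edgeR's TMM factors, a median of ratios, equal weight per cell, 0.5 and 2 times the minimum level, a ratio limit of 2, a prior of 5 CPM, subtraction of a 5% background and leaving out genes that may be background. Removal of doublets at 0.8% per 1000 barcodes was also among them and equalled the removal used. Chosen after seeing the data were comparisons within neutrophil clusters 5 and 7, without each gene's highest cell, among cells with Y-linked UMIs, and without Xist. Also chosen then was a comparison of neutrophils drawn in equal numbers from both libraries within 20 bins of UMIs per cell, over 200 draws. The male share of each WT class was taken as its Y-linked CPM relative to the same class of the other library. Gene positions were taken from GENCODE mouse release 21 on mm10. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-image 0.26.0, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 (TMM factors only).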

Results

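Immune cells infiltrating the gingiva of WT mice and of mice labelled Otud1-/- were profiled in 1 library each. OTUD1 is a deubiquitinase, an enzyme that removes ubiquitin from other proteins, and the study's title places its action in neutrophils and protein transport during periodontal inflammation. The kept cells numbered 11414 for WT and 6486 for the library labelled Otud1-/-. Cells of the latter held more UMIs, with a median of 4169.5 UMIs against 2082. Below, "higher" and "lower" mean in the library labelled Otud1-/- relative to the WT library. No difference between the libraries has a replicate check, and the 95% intervals of levels, ratios and shares cover counting error only, while those of list medians cover the spread between genes.

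Otud1 transcripts were higher, not lower, in the library labelled Otud1-/-. Over all barcodes the WT library held 834 Otud1 UMIs (18.6 CPM, 17.3 to 19.9) and the library labelled Otud1-/- held 1456 (33.0 CPM, 31.4 to 34.8). In kept cells the values were 622 UMIs (18.9 CPM, 17.4 to 20.4) and 1265 UMIs (33.2 CPM, 31.4 to 35.1), a ratio of 1.76 (1.60 to 1.94). The ratio was 2.26 (1.77 to 2.89) in T cells, 1.87 (1.58 to 2.22) in B cells and 1.66 (1.09 to 2.56) in dendritic cells. Its interval included no difference in monocytes/macrophages (1.17, 0.899 to 1.53), NK cells (0.981, 0.530 to 1.82) and neutrophils. In neutrophils the level was low in both libraries, with 23 UMIs (11.9 CPM, 7.55 to 17.9) and 27 UMIs (8.74 CPM, 5.76 to 12.7), a ratio of 0.734 (0.405 to 1.34). At least 1 Otud1 UMI was found in 4.92% (4.53 to 5.33) of WT cells and in 15.4% (14.5 to 16.3) of cells of the other library. After thinning every cell to 1000 UMIs, which left out 1280 WT cells and 282 of the other library, the shares were 2.16% (1.89 to 2.46) and 3.77% (3.31 to 4.28). No class known to lack Otud1 was at hand to set these shares against. In neutrophils, the lowest of the 6 classes compared, the unthinned shares were 2.10% at a median of 1550 UMIs and 3.02% at 2636.5 UMIs.

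Otud1 (ENSMUSG00000043415.5) lies on the plus strand of mouse chromosome 2, from 19657752 to 19660583 (mm10), as 1 transcript of 1 exon. Its coding sequence runs from 19658062 to 19659423, between a 5′ untranslated region from 19657752 to 19658061 and a 3′ untranslated region from 19659424 to 19660583, and 0 other annotated genes overlap it. The assay tags the 3′ end of a transcript. If the deleted part of the gene lies outside the tagged part, this count does not check the label. The level of Otud1 went against the label, so the second library is named only by its label, and every direction given here rests on that label.

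**Figure D1:**
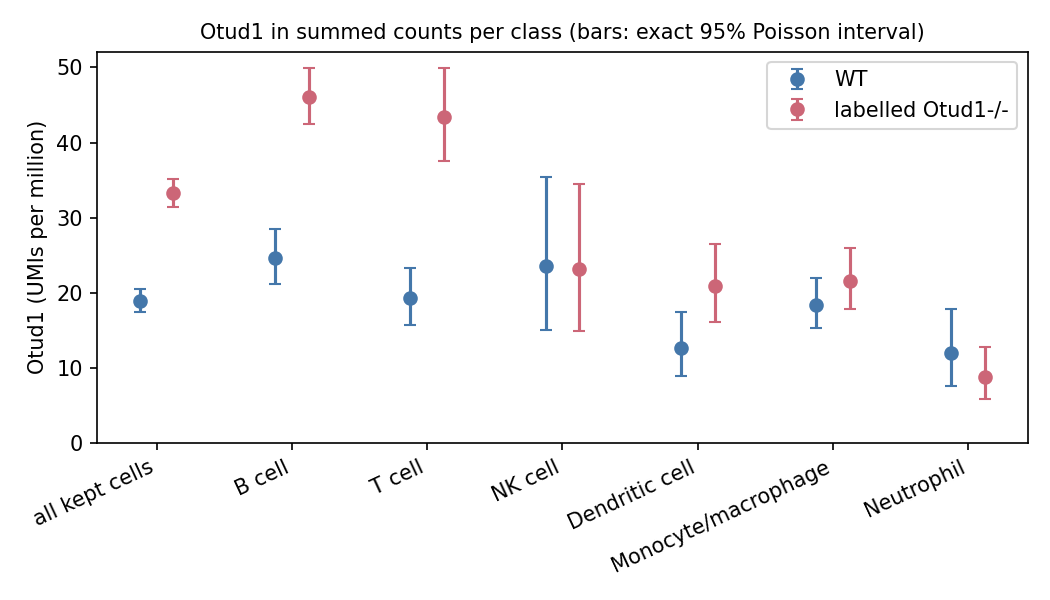
Otud1 level (CPM) in each cell class of the WT library and of the library labelled Otud1-/-, with exact Poisson 95% intervals of counting error. B cells stood at 24.6 and 46.1 CPM and T cells at 19.2 and 43.4 CPM, while the intervals of the 2 libraries overlapped in neutrophils (11.9 and 8.74 CPM).

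The sex-linked genes also separated the libraries. The WT library held 14449 UMIs of Xist, the RNA of the inactive X chromosome in female cells, and 6696 UMIs of the 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. The library labelled Otud1-/- held 5 Xist UMIs and 10368 Y-linked UMIs. Among kept WT cells, 3721 (32.6%) had an Xist UMI, 3262 (28.6%) a Y-linked UMI and 727 both. In the other library 4094 cells (63.1%) had a Y-linked UMI. The WT library thus held cells with female and cells with male transcripts, and the other library male transcripts with almost no Xist.

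The immune makeup of the gingiva differed between the libraries, with larger shares of B-like and neutrophil-like cells and a smaller share of monocyte- and macrophage-like cells in the library labelled Otud1-/-. Neutrophils, phagocytes that dominate acute periodontal inflammation, were 953 of the WT cells (8.35%, 7.85 to 8.87) and 862 of the other library (13.3%, 12.5 to 14.1), a difference of 4.94 points (3.97 to 5.93). With the erythroid and fibroblast classes left out and the unnamed clusters kept in, the neutrophil shares were 8.44% and 13.5%. B cells were 2511 WT cells (22%, 21.2 to 22.8) and 3053 cells (47.1%, 45.8 to 48.3), a difference of 25.1 points (23.6 to 26.5). Monocytes/macrophages were 2388 WT cells (20.9%, 20.2 to 21.7) and 497 cells (7.66%, 7.03 to 8.34), a difference of -13.3 points (-14.2 to -12.3). Plasmacytoid dendritic cells, the main producers of type I interferon, were 5.64% and 1.09%. T cells were 16.4% and 13.6%, other dendritic cells 7.08% and 4.56%, and NK cells 4.60% and 3.33%. Plasma cells were 2.44% and 1.33%, mast cells and basophils 1.32% and 0.339%, and ILC2 1.1% and 0.478%. The erythroid shares (0.754% and 0.956%) and fibroblast shares (0.324% and 0.493%) differed by less than their counting error.

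Within classes, the libraries also filled different clusters. Of the B cells, cluster 0 (Fcer2a, Ighd) held 1081 WT cells and 1800 of the other library. Among T cells, cluster 2 (Ctla4, Ikzf2) held 1201 and 346 cells, cluster 8 (Lef1, Tcf7) 349 and 433, and cluster 15 (Trdc, Il17a) 318 and 101. Among monocytes/macrophages, cluster 4 (C1qa, Cxcl9) held 940 and 62, cluster 3 (Vcan, F13a1) 813 and 229, and cluster 12 (Retnla, Mrc1) 446 and 174. With 1 library per group, a cluster mostly of 1 library may be that library, not a type. Clusters left unnamed by the naming rule, which was set after seeing the data, held 9.09% and 5.83% of cells. The shares follow a filter that removed 3.58% of WT barcodes and 14.2% of the other library's for over 15% mitochondrial UMIs, a gap in UMIs per cell, and doublet removal that took 10.6% and 6.49%. With at most 5% mitochondrial UMIs the B cell difference was 12.1 points and the neutrophil difference 10.9 points, and the NK difference changed sign. Among cells with Y-linked UMIs and no Xist the B cell difference was 14.0 points and the neutrophil difference 2.98 points.

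**Figure D2:**
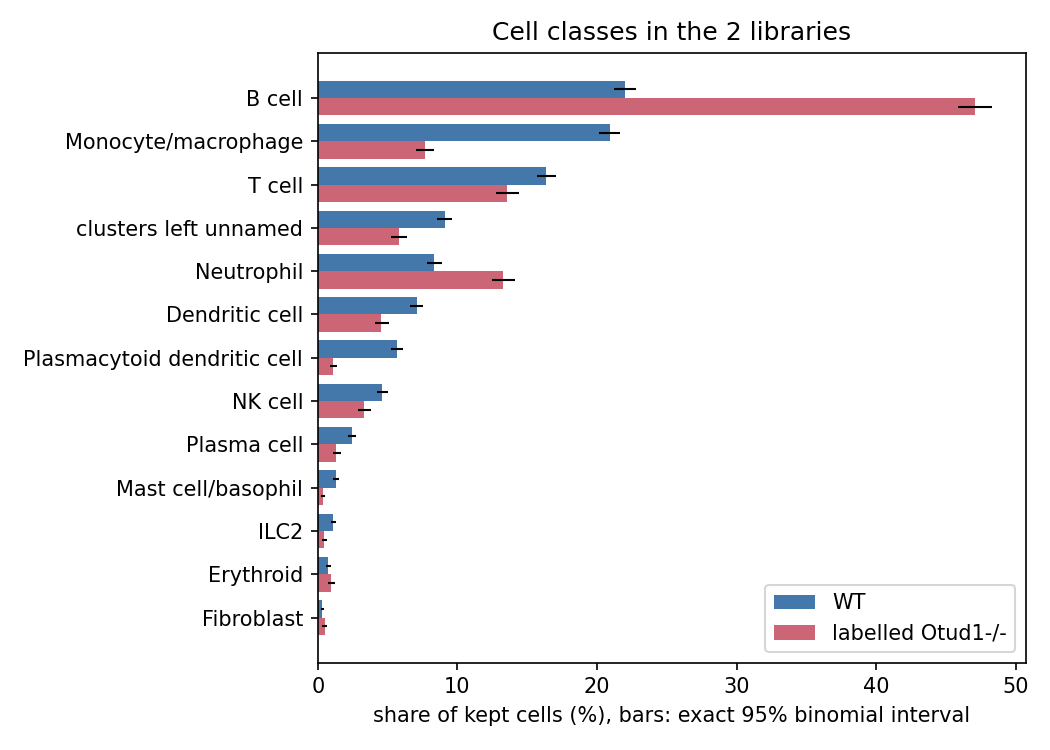
Share of kept cells (percent) in each cell class of the WT library and of the library labelled Otud1-/-, with exact Clopper-Pearson 95% intervals. The B cell share was 22% against 47.1%, the neutrophil share 8.35% against 13.3%, and the monocyte/macrophage share 20.9% against 7.66%.

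The neutrophil class joined 3 clusters that the libraries filled very differently. Cluster 5, led by Stfa2l1 and Cxcr2, held 155 WT neutrophils (16.3% of the class) and 776 of the other library (90.0%). Cluster 7, led by G0s2 and Retnlg, held 696 (73.0%) and 86 (9.98%). Cluster 26 was led by Ngp, Camp and Ltf, genes of secondary granules made in immature neutrophils. It held 102 WT cells and 0 of 862 in the other library, which allows this cluster a share of up to 0.348%. That limit is for the cluster, not for all cells with such genes. In cluster 5, Camp had 3284 UMIs in 23 cells of the other library and 1481 UMIs in 4 WT cells. Transcripts of other cell types moved with these clusters. WT cells of cluster 7 held B cell genes at 90.0% and T cell genes at 60.8% of the level in the whole WT library, against 16.0% and 10.7% for cluster 7 of the other library. In cluster 5 the B cell genes stood at 8.73% and 7.17%. S100a8 and S100a9, the calprotectin genes of neutrophils, together stood at 42135 and 71336 CPM in cluster 7 and at 103037 and 107117 CPM in cluster 5. Cd79a, a B cell receptor gene, was detected in 45.8% of WT neutrophils at a median of 1550 UMIs and in 10.1% of the others at 2636.5 UMIs. In T cells, which should lack Cd79a, the shares were 44.7% and 20.3% at medians of 2130.5 and 4676 UMIs, so the shares in neutrophils are at or near background. Ribosomal protein genes took a median of 18.2% of UMIs in WT cells of cluster 7, 5.50% in those of the other library, and 4.03% and 3.91% in cluster 5.

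**Figure D3:**
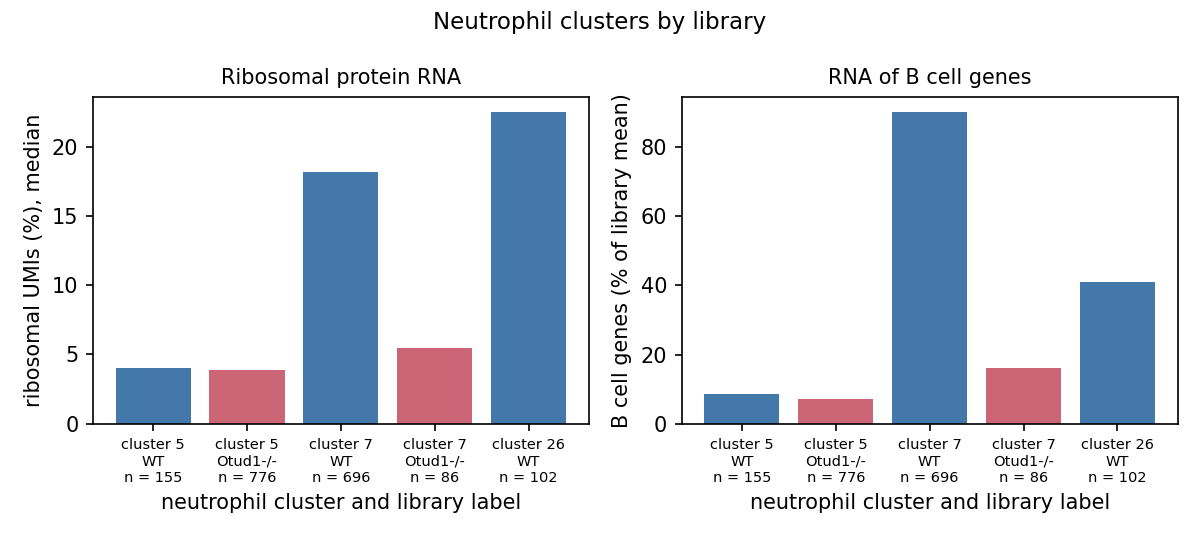
Neutrophil clusters 5, 7 and 26 in each library, with the number of cells of each. Bars show the median share of UMIs from ribosomal protein genes. Beside it stands the level of B cell genes as a percentage of the level in the whole library. Cluster 5 held 16.3% of WT neutrophils and 90.0% of those of the library labelled Otud1-/-, and cluster 26 held 0 cells of the latter.

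Over the whole neutrophil class, the median log2 ratio was negative for ribosomal protein and MHC class II genes and positive for chemotactic receptor and glycolysis genes, and all 4 medians were nearer to 0 within cluster 5. Of 2267 genes compared, 574 were at least 1.5-fold higher and 529 at least 1.5-fold lower, of which 2 and 117 may be background RNA. Scaling decided much of this split. TMM factors added 0.61 to every log2 ratio and a median of ratios 0.68, and the counts became 1293 higher and 256 lower, and 1369 and 236. Most WT cells of this comparison were in cluster 7 and most of the others in cluster 5. Of 546 genes higher in the class among 1421 genes also compared within cluster 5, 496 had the same direction there and 80 also passed 1.5-fold. Of 175 genes lower in the class, 96 had the same direction and 29 passed. These counts are no independent check, as cluster 5 is part of the class and holds 776 of its 862 cells of the other library. The median log2 ratio over all genes compared within cluster 5 was 0.16, so a positive direction was common there.

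Among the 12 highest genes were the protease inhibitor genes Stfa1 (log2 ratio 2.80, 2.35 to 3.35) and Stfa2l1 (1.86, 1.71 to 2.01). Genes of metabolism followed. Pfkfb3, a driver of glycolysis, stood at 1.77 (1.54 to 2.02), Sgms2 of sphingomyelin synthesis at 1.75, Alas1 of haem synthesis at 1.73, Gpat3 of glycerolipid synthesis at 1.68 and the glycerol kinase gene Gk at 1.65. Anxa11 (1.65), an annexin, and Selenon (1.57), a selenoprotein, completed this set. Within cluster 5 these 9 genes were higher too, from 0.68 for Selenon to 1.40 for Stfa1. Cluster 5 holds most neutrophils of the library labelled Otud1-/-, so this is no independent check. The remaining 3 of the 12 rested on single cells. One cell held 363 of 364 Elane UMIs of that library, 1 cell 291 of 295 Prtn3 UMIs and 1 cell 716 of 777 Hbb-bs UMIs. Without each gene's highest cell per library their log2 ratios went from 5.26 to -1.32, from 2.68 to -2.60 and from 1.82 to -1.44.

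Of the 12 lowest genes, 6 encode ribosomal proteins, namely Rps28 (-2.57, -2.67 to -2.48), Rpl38 (-2.38), Rps29 (-2.32), Rpl6 (-2.23), Rps26 (-2.22) and Rpl22 (-2.20), with the mitochondrial gene mt-Nd4l at -2.23. The others were the tubulin gene Tubb5 (-2.46), Bola2 (-2.43), the chromatin-related genes Ptma (-2.27) and Set (-2.20), and the acute-phase gene Saa3 (-2.95, -3.48 to -2.53). One WT cell held 49.3% of the WT Saa3 UMIs, and without the highest cells Saa3 stood at -2.21. Tubb5 had the other direction within cluster 5 (0.18).

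The gene lists fixed beforehand showed the same division. Of 77 ribosomal protein genes, 0 were at least 1.5-fold higher and 76 lower (median log2 ratio -1.80, percentile 0), with Rpl10a at -2.71 (may be background). MHC class II genes, which present antigen to T cells and are abundant in B cells, had 1 of 12 higher and 11 lower (median -2.20, percentile 0), with Cd74 at -2.56 (may be background). All 13 mitochondrially encoded genes were lower (-1.39, percentile 1.02). Of 56 nuclear genes of oxidative phosphorylation 37 were lower and 0 higher (-0.95, percentile 0), and of 32 proteasome genes 26 were lower and 0 higher (-1.01, percentile 0). Lymphocyte genes were lower too. Type 17 genes had 5 of 8 lower (-1.46, but 0.41 at 2 times the minimum level and 0.46 without genes that may be background), cytotoxic genes 3 of 3 (-2.39, with Gzma at -2.91, may be background), the 1 measured regulatory T cell gene, Icos, stood at -2.73 (may be background), and 6 of 7 cell cycle genes were lower (-1.41, but 0.0069 in cluster 7). The first 5 of these lists were also measured with RNA of other cells taken out. RNA of other classes was estimated from 394 marker genes, relative to cluster 5 of the same library. On that estimate it made up 40.7% of the RNA of WT neutrophils and 0.449% of the others. Cluster 5 is itself 90.0% of the neutrophils of the library labelled Otud1-/-, so the low value there was set by the reference. In WT, where cluster 5 is 16.3%, differences of clusters 7 and 26 from cluster 5 could count as RNA of other classes. With the estimated RNA of other classes taken out, the median was -0.78 for ribosomal genes, 0.27 for MHC class II, -0.93 for mitochondrially encoded genes, -0.02 for the proteasome and -0.16 for oxidative phosphorylation.

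Receptors for chemotaxis and adhesion had 17 of 27 genes at least 1.5-fold higher and 1 lower (median 0.78, percentile 99.97), but 0 of 28 higher and 5 lower within cluster 5 (0.05). Il1r2, the decoy receptor for interleukin 1, stood at 1.39 (1.32 to 1.46), the nucleotide receptor gene P2ry2 at 1.39 and Cxcr2, the main chemokine receptor of neutrophils, at 1.18 (1.06 to 1.3). In glycolysis and hypoxia 10 of 25 were higher and 1 lower (0.45, percentile 99.1), led by Pfkfb3, Ndrg1 (1.35, may be background) and Hk3 (1.14). Interferon-stimulated genes had 7 of 33 higher and 4 lower (0.26, percentile 98.9), with Isg15 at 0.86 and Bst2 at -1.85 (may be background). NF-kB targets and inflammatory cytokines had 13 of 32 higher and 1 lower (0.42, percentile 78.3), with Tnfsf14 at 1.41 and Acod1 at 0.89. Chemokines had 2 of 12 higher and 6 lower (-0.97, percentile 2.69), with Cxcl1 at -1.71. These lists were also measured mostly in cluster 7 for WT, where S100a8 and S100a9 were lower as given above.

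The remaining lists included granule, oxidase and stress genes. Secondary and tertiary granule proteins had 5 of 21 higher and 1 lower (0.44, percentile 83.0), with Slpi at 1.5 and Adam8 at 1.47. Primary granule proteins had 2 of 7 on each side (-0.20, percentile 51.7). The 2 higher were Elane and Prtn3, which rested on single cells, and the median was -0.91 without each gene's highest cell. NADPH oxidase and nitric oxide genes had 2 of 10 on each side (0.42, percentile 63.5), with Cybb at -1.18. Apoptosis and survival genes had 7 of 23 higher and 3 lower (0.24, percentile 88.8), and mediators of tissue breakdown 5 of 14 higher and 1 lower (0.37, percentile 68.4). Genes of the unfolded protein response had 2 of 21 higher and 10 lower (-0.40, percentile 5.46), other deubiquitinases 0 of 20 higher and 7 lower (-0.35, percentile 44.1), MHC class I genes 0 of 19 higher and 7 lower (-0.37, percentile 7.28), and dissociation-associated early genes 3 of 27 higher and 7 lower (-0.28, percentile 1.54). Under TMM factors and the median of ratios the medians of these last 4 lists and of primary granule proteins turned positive. The 3 haemoglobin genes were higher (2.23) and turned to -1.02 without their highest cells.

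Genes of protein transport, the subject of the study's title, did not move together in neutrophils. Over the 6 lists, 26 of 160 measured genes were at least 1.5-fold higher and 38 lower, with a median of -0.13 (-0.26 to 0.06) at percentile 77.9, and the median turned to 0.47 under TMM factors and 0.54 under the median of ratios. These lists were chosen by the study's title and are not independent evidence. Genes of translocation into the endoplasmic reticulum had 0 of 21 higher and 12 lower (-0.69, percentile 1.44), with Sec61g, a subunit of the translocation channel, at -1.62. Nuclear import and export genes had 1 of 14 higher and 8 lower (-0.70, percentile 5.67), with Ranbp1 at -2.50 (may be background). COPI and COPII vesicle genes had 2 of 30 higher and 6 lower (-0.14, percentile 72.9), a median that also turned positive under both scalings. Rab GTPases and their regulators had 10 of 31 higher and 3 lower (0.27, percentile 95.5), with Rab27a, which acts in granule release, at 0.76 and Gdi2 at -1.42. SNAREs and exocytosis genes had 5 of 24 higher and 3 lower (0.06, percentile 97.1), with Stx11 at 1.40 (1.24 to 1.58) and Snap23 at 1.01. Endosomal sorting genes had 8 of 40 higher and 6 lower (0.03, percentile 91.3), with Vps18 at 1.37 and Snx5 at -2.13 (may be background). Rab27a was named after its value was seen. With RNA of other cells taken out as above, the median of the 6 lists was 0.05, and within cluster 5 it was 0.03 over 152 genes (11 higher, 19 lower, percentile 91.4). In all non-neutrophil classes together, 0 of 186 transport genes passed 1.5-fold (-0.01, percentile 43.7). By class, NK cells had 8 of 180 higher and 9 lower (0.06), monocytes/macrophages 5 of 185 and 0 (0.08, percentile 98.9), dendritic cells 1 of 171 and 2 (0.02, percentile 99.3), T cells 1 of 180 and 2, and B cells 0 of 175 in either direction.

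**Figure D4:**
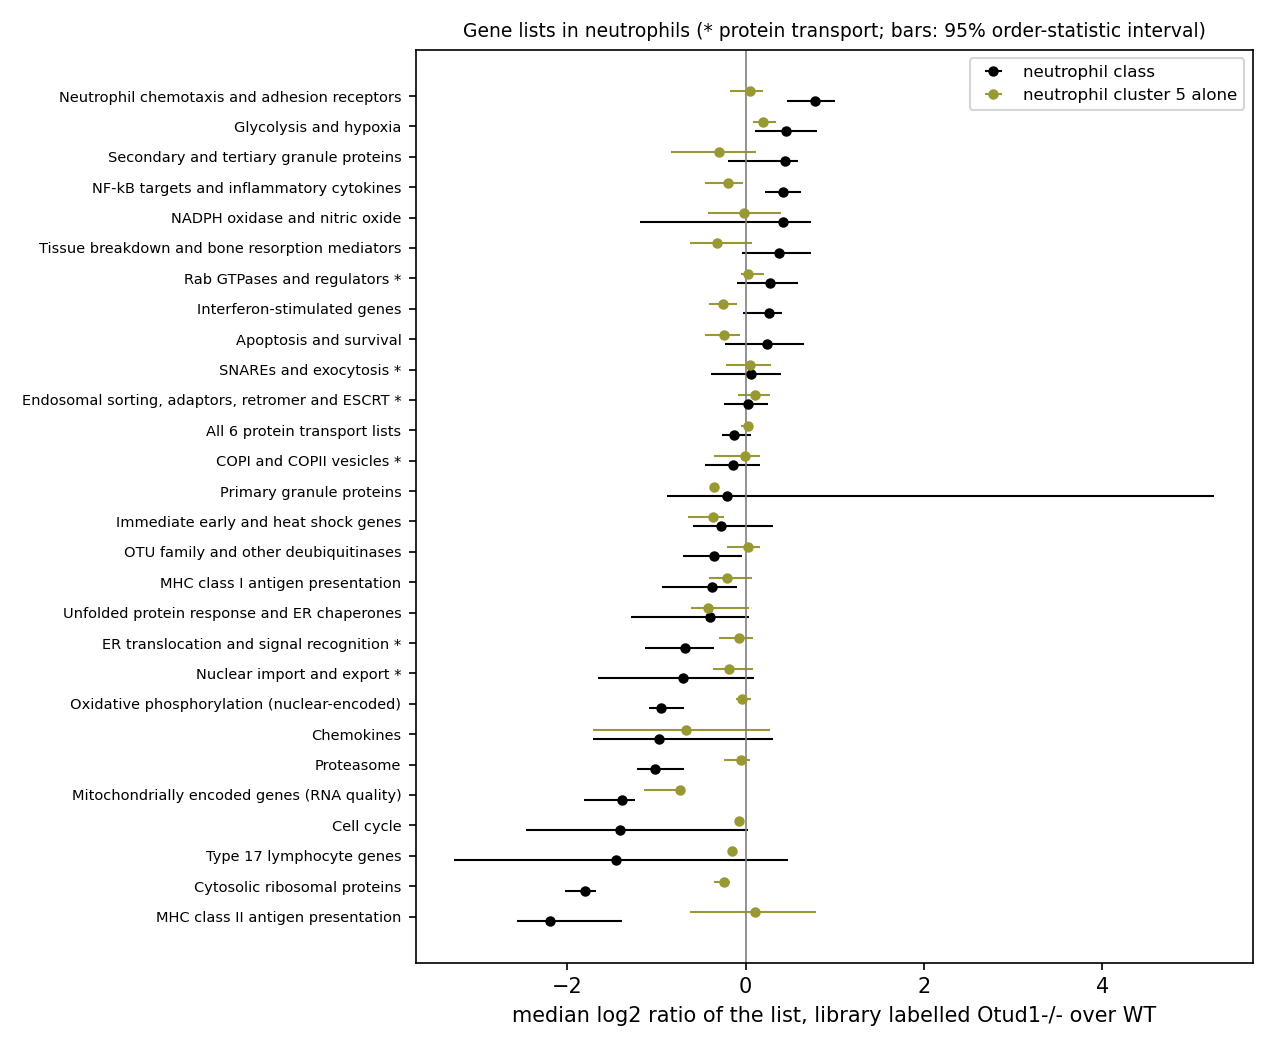
Median log2 ratio (library labelled Otud1-/- over WT) of each gene list in the neutrophil class and in neutrophil cluster 5, with 95% intervals of the median where at least 6 members were measured, and protein transport lists marked *. Ribosomal proteins stood at -1.80 in the class and chemotaxis and adhesion receptors at 0.78, while the 6 transport lists together stood at -0.13, which turned positive under both other scalings (0.47 and 0.54).

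Cluster 5 alone, chosen after seeing the data as the neutrophil cluster with the lowest ribosomal share, compared cells of like ribosomal and B cell RNA content, though T cell genes stood at 15.9% of library level in WT and 6.58% in the other library. In it, the median log2 ratios of chemokine, interferon-stimulated and early response genes lay below those of nearly all random lists. Of 1457 genes compared, 109 were at least 1.5-fold higher and 67 lower, 254 and 35 under TMM factors (a shift of 0.16) and 295 and 31 under the median of ratios (0.19). The comparison set 155 WT cells against 776. Among the 12 lowest genes were Egr1 (-1.88, -2.01 to -1.75) and Nr4a1 (-1.07) of the immediate early response, the cytokine gene Il1a (-1.28, -1.52 to -1.04), the transcription factor gene Irf1 (-1.24), the adhesion gene Icam1 (-1.06) and Ptgs2 (-1.02), which makes prostaglandins. Mrgpra2a stood at -1.05, mt-Nd3 at -1.27 and Mrpl52 at -1.01. Saa3 (-4.00), Camp (-1.28) and Chil3 (-1.09) rested on single WT cells, which held 113 of 132, 1010 of 1481 and 182 of 256 of their UMIs. Without each gene's highest cell these stood at -1.47, 0.12 and 0.28. The 12 highest included the inhibitor genes Cstdc5 (1.68, 0.93 to 2.60) and Stfa1 (1.40), Cd93 (1.53), Rnh1 (1.39), the integrin gene Itga5 (1.24), Alas1 (1.22), Anxa11 (1.20), Pfkfb3 (1.12), Ptprj (1.11), Plec (1.09) and the endosomal gene Vps18 (1.06). Hbb-bs (2.62) rested on 1 cell and stood at -1.07 without it.

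Of the lists in cluster 5, 7 of 11 chemokine genes were lower and 0 higher (-0.67, percentile 0.02), with Cxcl1 at -1.81 (-2.28 to -1.36). Genes of the unfolded protein response had 7 of 21 lower and 1 higher (-0.42, percentile 0), and early and heat shock genes, which also respond to tissue dissociation, 9 of 25 lower and 0 higher (-0.37, percentile 0.02). Interferon-stimulated genes had 7 of 34 lower and 1 higher (-0.26, percentile 0.22), the reverse of the sign in the whole class. NF-kB targets had 7 of 32 lower and 1 higher (-0.19, percentile 0.15), a median that turned positive under the median of ratios. Tissue breakdown mediators had 3 of 14 lower and 1 higher (-0.32, percentile 0.11). Secondary granule proteins had 9 of 23 lower and 2 higher (-0.30), but stood at 0.12 without each gene's highest cell. Glycolysis genes had 5 of 25 higher and 3 lower (0.19, percentile 97.9), and chemotaxis receptors 0 of 28 higher and 5 lower (0.05, percentile 50.3). Without each gene's highest cell the medians were -0.69 for chemokines, -0.27 for the unfolded protein response, -0.29 for early genes, -0.12 for interferon-stimulated genes, -0.14 for NF-kB targets and -0.27 for tissue breakdown. This removal took 1 of 155 WT cells but 1 of 776 others per gene, which by itself can raise a ratio. Medians of other lists rose with it, from 0.03 to 0.11 for protein transport and from -0.04 to 0.07 for oxidative phosphorylation. All 12 measured mitochondrially encoded genes were lower (-0.73). Ribosomal genes, by which the cluster was chosen, had 13 of 77 lower and 0 higher (-0.24), and MHC class II stood at 0.11 over 8 genes.

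In monocytes and macrophages the lists of tissue breakdown and glycolysis genes had positive medians. Timp1, an inhibitor of matrix metalloproteinases, stood at 10.6 CPM in WT and 89.4 CPM (log2 ratio 3.01, 2.71 to 3.46), Spp1, which encodes osteopontin, at 2.04 (1.86 to 2.25), and S100a10 and Anxa2, whose products bind each other, at 1.36 and 1.33. None of these was screened for background RNA from fibroblasts, which were too few. Saa3 (-2.05), the alternative activation gene Retnla (-1.86), complement factor B (Cfb, -1.56) and Ly6i (-1.39) were lowest. Unnamed cluster 19, with 22 WT cells and 185 of the other library, has Cfb and Ly6i among its top genes and is not part of this class. Of 2711 genes, 107 were higher and 68 lower. Tissue breakdown mediators had 9 of 20 higher and 0 lower (0.34, percentile 100), with Ctsk, the collagenase of osteoclasts, at 6.46 (may be background, 3.46 without the highest cells). Glycolysis genes had 8 of 24 higher and 0 lower (0.42, percentile 100), with Pkm at 0.81 and Tpi1 at 0.80, and NF-kB targets 4 of 33 higher and 0 lower (0.26, percentile 100). Among MHC class II genes 0 of 12 passed in either direction (-0.03). Mitochondrially encoded genes, a mark of RNA quality, moved too, with 3 of 13 lower and 0 higher (-0.25, percentile 0.035). Clusters 4 and 3 held most WT cells of this class, and clusters 3 and 12 most cells of the other library. Medians per cell were 2001 and 8898 UMIs.

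In NK cells and T cells the median of the cytotoxic genes lay above that of random lists and the median of the MHC class II genes below. In NK cells Ifng, the interferon gamma gene, stood at 1.91 (1.53 to 2.32), the chemokine gene Cxcl10 at 1.65, Thy1 at 1.35 and Stx11, which acts in cytotoxic granule release, at 1.26. One cell held 26.4% of the Ifng UMIs, and without the highest cells Ifng stood at 1.53. Mef2c (-1.50), Lyn (-1.06), Foxn3 (-1.03) and Zfp36 (-0.94) were lowest. Of 1529 genes 94 were higher and 83 lower, 138 and 69 under TMM factors and 153 and 63 under the median of ratios. Cytotoxic genes had 7 of 13 higher and 0 lower (0.60, percentile 100), with Xcl1 at 1.15. MHC class I genes had 6 of 20 higher and 0 lower (0.40, percentile 100), and proteasome genes 8 of 34 and 0 (0.31, percentile 99.97). Dissociation-associated early genes had 8 of 25 lower and 0 higher (-0.09, percentile 1.89, positive under the median of ratios). MHC class II genes had 11 of 11 lower (-1.66), mitochondrially encoded genes 3 of 13 lower and 0 higher (-0.23), and Cd79a was found in 32.6% of WT NK cells and 14.4% of the others at medians of 1335 and 4186.5 UMIs.

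In T cells 17 of 2603 genes were higher and 84 lower. Ifng stood at 1.82, but 1 cell held 312 of its 378 UMIs, and without the highest cells it stood at -0.54. Fam110a stood at 1.53, Klk8 at 0.76 and Mpp7 at 0.75. The immediate early gene Fos (-1.22), Mef2c (-1.21), Plac8 (-1.17) and Ly86 (-1.16), the last 3 also expressed in B cells or myeloid cells, were lowest. Cytotoxic genes had 5 of 11 higher and 0 lower (0.40, percentile 100, and 0.30 without the highest cells), with Gzma at 1.77 (may be background) and Klrk1 at 0.98. Unnamed cluster 25, with Gzmk and Gzmb among its top genes, held 111 WT cells and 10 of the other library. It is part of neither the T cell nor the NK cell class, so its cytotoxic genes are missing mostly from the WT side. Type 17 genes had 1 of 13 higher and 0 lower (-0.04), with Il17a at 0.63. Regulatory T cell genes had 0 of 10 past 1.5-fold (0.11). MHC class II genes had 7 of 11 lower (-0.75), and with them the B cell gene Cd79a, found in 44.7% and 20.3% of T cells at medians of 2130.5 and 4676 UMIs. Dissociation-associated early genes had 7 of 25 lower and 0 higher (0.06, percentile 72.5). Cluster 2 held most WT T cells, while clusters 8 and 2 held most of the others.

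B cells, the class with the most cells in both libraries, differed least by number of genes. Of 2626 genes 8 were higher and 43 lower, or 22 and 24 under both other scalings, which shifted every log2 ratio by 0.11. Bmyc (0.76), Emp3 (0.72), Strap (0.68) and the survival gene Bcl2a1d (0.66) were highest. Fos (-1.70, -1.85 to -1.58), Rgs1 (-0.94), AY036118 (-0.87) and the stress response gene Ppp1r15a (-0.85) were lowest. Early genes that respond to tissue dissociation had 6 of 24 lower and 0 higher, with a median of -0.07 (percentile 14.2) that turned positive under both other scalings. Cell cycle genes had 4 of 17 lower and 0 higher (-0.37, percentile 0), with Mki67 at -0.92. Clusters 0 and 1 held most B cells of both libraries.

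In dendritic cells 47 of 2450 genes were higher and 84 lower, or 112 and 44 under TMM factors (a shift of 0.13) and 118 and 38 under the median of ratios (0.15). Fam110a (1.68), the costimulatory ligand gene Tnfsf9 (1.29), Nupr1 (1.16) and Id3 (1.0) were highest, and Pdcd4 (-1.41), Satb1 (-1.07), mt-Nd4l (-1.07) and Ifi205 (-1.06) lowest. NF-kB targets had 5 of 29 higher and 0 lower (0.27, percentile 100), with Il1b at 0.92. MHC class II genes stood at 0.28 with 0 of 12 past 1.5-fold. The 8 regulatory T cell genes measured in this class had 5 lower and 0 higher (-1.13), led by Ikzf2, Ctla4 and Icos, which may be background. Mitochondrially encoded genes had 3 of 13 lower and 0 higher (-0.36). Cluster 6 held most dendritic cells of both libraries, and medians per cell were 2486 and 10087 UMIs.

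Across classes, 6 of 1101 genes compared in all 6 classes were at least 1.5-fold lower in each and 0 higher. These were Xist, Gm8797, mt-Atp8, Rps29, Rps28 and mt-Nd4l, named after their values were seen. Across genes, which are not independent replicates, the log2 ratios of the 5 other classes correlated with each other at Pearson r from 0.58 to 0.77, and from 0.38 to 0.68 without Xist. For neutrophils against all non-neutrophil classes together, r was 0.11 and Spearman's rho -0.03 over 1734 genes, and r was -0.04 without Xist. By class, r was 0.43 for monocytes/macrophages, 0.38 for dendritic cells, 0.38 for NK cells, 0.24 for T cells and 0.12 for B cells, the last turning to -0.05 without Xist. For cluster 5 against all non-neutrophil classes, r was 0.03 and rho 0.20 over 1045 genes.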

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

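Among the tests below, those of the sex of the animals, of exchanged labels and of the mitochondrial limit were chosen after the result was seen, and that of class makeup before its value was computed.

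In the library labelled Otud1-/-, 14.2% of barcodes exceeded 15% mitochondrial UMIs, against 3.58% in the WT library. B cells were the class with the largest difference in share, and the limit could have removed more cells of other classes from that library. Of the barcodes over the limit, 1069 of that library and 467 of the WT library had at least 200 genes. Even with the former all counted as other classes and the latter all as B cells, the B cell difference of 25.1 points would be 15.3. For these barcodes, this limit is therefore not the whole cause. From Y-linked UMIs relative to the other library, and if these genes have the same level per male cell in both, 65.8% of WT cells were male. On that estimate at most 30.8% of these could be B cells, against 47.1% in the other library. The estimate has no interval, and RNA of other cells in WT droplets could raise the male share and so lower this limit. WT cells with Y-linked UMIs and no Xist were B cells in 31.2% (29.4 to 33.1). In the other library, cells with Y-linked UMIs were B cells in 45.2%. If the estimate holds, animals of both sexes in the WT library are not the whole cause, and the genotype stays an untested explanation.

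The WT library held 14449 Xist UMIs and the other library 5, while Y-linked UMIs were found in both. Every comparison of all kept cells therefore sets cells of female and male origin against cells of male origin, and sex, animal and label differ together.

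Otud1 was higher in the library labelled Otud1-/-. With each class given its WT weight the ratio was 1.66 (1.5 to 1.83), so the larger share of classes with high Otud1 is not the whole cause. In a further estimate, male WT cells were given the Otud1 level of the other library, class by class. Female cells were given that of WT cells with at least 3 Xist UMIs (19.6 CPM). The WT library would then be expected at 27.4 CPM (25.5 to 29.3) against 18.9 found (17.4 to 20.4). If the male share estimated from Y-linked UMIs holds, the sex of the animals is not the whole cause either. Otud1 stood at 20.6 CPM (17.8 to 23.8) in WT cells with Y-linked UMIs and no Xist. It stood at 19.4 CPM (16.7 to 22.4) in WT cells with Xist and no Y-linked UMI. Cells with Y-linked UMIs in the other library stood at 32.9 CPM (30.8 to 35.1). The library labelled WT held 834 Otud1 UMIs and the other 1456, and the deleted part was not given in the sources used here. A deletion of the counted sequence would leave few or no such UMIs in whichever library was Otud1-/-. An exchange of labels would therefore also need a deletion outside the tagged end of the transcript. These counts cannot tell whether the libraries carry each other's labels. The genotype stays an open explanation for this difference.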

How the results depend on the processing

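No paired analysis was possible because each genotype has 1 library. Comparisons within neutrophil clusters, without each gene's highest cell, among cells with Y-linked UMIs and no Xist, and without Xist were chosen after the result was seen. Where a value changed, the cause was not tested. Removing doublets at a fixed rate per 1000 barcodes equalled the removal used. Share of kept cells: B cell difference 25.1 points became 12.1 with at most 5% mitochondrial UMIs, 21.3 at resolution 2, 17.5 with libraries clustered alone and 14.0 among Y-linked cells. Share of kept cells: Monocyte/macrophage difference -13.3 points became -11.9 at 5%, -9.32 at resolution 0.5, -11.7 at resolution 2, -8.48 alone and -8.96 among Y-linked cells. Share of kept cells: NK cell difference -1.27 points reversed to 0.0525 at 5% and 0.452 among Y-linked cells. The neutrophil difference of 4.94 points (Cell class shares) became 6.16 with at least 500 genes, 10.9 at 5%, 7.09 without doublet removal and 2.98 among Y-linked cells. The log2 ratio of Otud1 in kept cells went from 0.80 to 0.66 among Y-linked cells. Of neutrophil genes, the 574 higher became 1293 (TMM factors), 1369 (median of ratios), 192 (ratio limit 2), 109 (cluster 5) and 68 (cluster 7). The 529 lower became 256, 236, 343, 67 in cluster 5, 250 at 2 times the minimum level, 309 after thinning and 179 among Y-linked cells. The median of the protein transport lists went from -0.13 to 0.47 (TMM factors), 0.54 (median of ratios) and 0.081 (2 times the minimum level). The correlation of neutrophils with the other classes went from 0.11 to -0.12 after thinning, 0.057 without genes that may be background, 0.026 in cluster 5 and -0.041 without Xist. Of 513 list medians 435 stayed, 70 moved and 8 reversed. Lists with fewer than 6 measured genes, haemoglobin among them, were not part of these 513, nor was the pooled transport list. Reversed means a change of sign in a list whose median lay outside the central 95% of its random lists, so sign changes of other lists are not among these 8, which were interferon-stimulated genes (-0.26) and MHC class II (0.11) in cluster 5, type 17 genes at 2 times the minimum level (0.41) and without background genes (0.46), cell cycle genes in cluster 7 (0.0069), and dissociation-associated genes under TMM factors (0.33) and the median of ratios (0.40), which shift all genes alike and leave a list's place among other genes, and thinning (0.038). Named gene in neutrophils: Elane reversed with libraries alone (-1.87) and without top cells (-1.32), and likewise Prtn3 alone (-3.02), in cluster 5 (-1.16) and without top cells (-2.60). Hbb-bs reversed with equal weights (-0.49), at 5% mitochondrial UMIs (-1.35), after thinning (-0.48), in cluster 7 (-0.70) and without top cells (-1.44). Saa3 reversed in cluster 7 (0.68) and Tubb5 in cluster 5 (0.18). Without top cells Ifng reversed in T cells (-0.54), and Hbb-bs (-1.07), Camp (0.12) and Chil3 (0.28) in cluster 5.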

Other observations

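Of the tests below, the comparison of cells with Xist and cells with Y-linked UMIs and the matching on depth were chosen after the result was seen, and the other tests of the ribosomal genes before their values were computed.

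Within the WT library, 2994 cells with Xist and no Y-linked UMI and 2535 cells with the reverse differed in makeup, although single UMIs separate the sexes only in part and 727 cells held both. B cells were 21.9% (20.4 to 23.4) of the former and 31.2% (29.4 to 33.1) of the latter, neutrophils 4.61% and 8.80%, and plasmacytoid dendritic cells 7.95% and 3.79%. In the library labelled Otud1-/-, cells with Y-linked UMIs were B cells in 45.2%, neutrophils in 11.8% and plasmacytoid dendritic cells in 1.34%. For these 3 classes, chosen after the values were seen, these cells of the WT library differed in the same direction as the 2 libraries. T cells (18.8% with Xist and 15.3% with Y-linked UMIs), NK cells (5.61% and 2.92%) and plasma cells (3.24% and 1.34%) did so too. Monocytes/macrophages (18.4% and 17.4%) and dendritic cells (6.88% and 6.75%) hardly differed between these 2 sets of cells. ILC2, mast, erythroid and fibroblast cells went the other way, each with overlapping intervals. The male share estimated from Y-linked UMIs, 65.8% over all WT cells, differed from this split in part. It was lower in neutrophils (62.1%), higher in dendritic cells (74.4%) and near 65.8% in NK cells (65.0%). For B cells (74.6%), plasmacytoid dendritic cells (54.7%), T cells (54.6%) and plasma cells (53.8%) it went the same way as the split. The split by single UMIs therefore does not measure sex alone.

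Some unnamed clusters were nearly of 1 library. Cluster 19, with Gbp2, Cfb and Cxcl9, held 22 WT cells and 185 of the other library. Cluster 24, with Il22, held 126 and 7, and cluster 25, with Gzmk, Gzmb and histone genes, held 111 and 10.

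Ribosomal protein genes were lower in the neutrophil class of the library labelled Otud1-/- at a median of -1.80. With 507 neutrophils of each library matched on UMIs per cell the median was -1.83 (-1.91 to -1.69 over 200 draws), and without the immature cells of cluster 26 it was -1.68, so neither depth per cell nor these immature cells are the whole cause. With RNA of other classes taken out of the neutrophil profile it was -0.78, so RNA of other cells in WT droplets cannot be told apart from a difference within neutrophils. The genotype stays an untested explanation here too.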
